A study of Drosophila melanogaster with 6 samples.

How the data were processed

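Poly(A) RNA from dissected ovaries of Drosophila melanogaster was measured in 6 libraries, 3 of genotype RanBP9D1 over BSC469 and 3 of w1118 over BSC469. RNA was extracted with TRIzol and libraries were made with a directional NEBNext Ultra II kit, per the labels' protocols. The values deposited by the authors are raw read counts per gene, 1 table per library, with the position and genomic length of each gene. Per the submitters' processing notes, TopHat2, HTSeq and DESeq2 were used with the builds dm6 and BDGP6. Their versions, their roles, the annotation release and the strand setting are not given in the sources used here. The counts are whole numbers with totals of 21583524 to 26483578 per library.

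Every table lists the same 17559 genes. Gene symbols were taken from the reference annotation of the BDGP6 build by gene ID for 17253 genes, and by position, with a reciprocal overlap of at least 90%, for a further 209, and 16960 genes had identical coordinates in both. RanBP9 of the labels was matched to the current symbol Ipo9 as its older name. Of the entries in the fixed gene lists, 3 matched no gene (phm, arts and nos) and were left out. The strand of the counting was checked on genes that lie inside an exon of another gene with at least 1000 counts. On the opposite strand, 19 of 51 such genes had 10 or more counts, and together they held 3.16% of the counts of their hosts. On the same strand, 0 of 48 did, and the genes overlapping there have 0 or few counts in every library (cup, Polr2D, Orc3 and mRpL53 among them), so genes overlapping on the same strand are reported as uncertain and a missing value there is not a sign of missing expression.

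Differential expression was computed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 8110 and set aside 9449. Libraries were scaled with TMM factors (0.986 to 1.01), and a quasi-likelihood negative binomial model with robust dispersion was fitted to mutant against control without covariates. The p-values were adjusted with the Benjamini-Hochberg method and called under 0.05 with no minimum fold, and the common biological coefficient of variation was 6.63%. Log2 fold changes are mutant over control with their standard errors, and CPM values (counts scaled to a common library total) use the TMM factors, with the sample SD over 3 libraries. For genes with 3 or fewer counts summed over a group, the ratio of the scaled group sums is given with its exact (Clopper-Pearson) 95% interval. For groups at 0, the ratio against a floor of 3 counts over the group is given as a lower bound. No molecular identifiers are described, so reads are not known to be independent molecules.

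Before the data were examined, the main design, the alternatives, 33 gene lists and the rule for the genes named in the text were fixed. The rule named Ipo9 and the 6 actin genes. It also named the 6 largest and 6 smallest log2 fold changes among called genes with non-overlapping groups and a mean of at least 5 CPM, and the same again among genes with a proper symbol. Up to 4 members with the smallest p per list, the 3 genes with the smallest p per direction, and the 3 most abundant tested genes completed it. The text names a part of these, and also Yp1, Yp2, genes of the added lists, untested marker genes and genes nearly absent from a group, which were chosen after their values were seen. The lists covered chorion, vitelline membrane, follicle cells, yolk uptake, endocycle and amplification, germline and maternal mRNAs, the piRNA pathway, ecdysone synthesis and signalling, actin isoforms, actin regulators, MRTF and SRF, nuclear transport, RNA polymerase II subunits, initiation and elongation, cytosolic and mitochondrial ribosomal proteins, initiation factors, chaperonin, proteasome, oxidative phosphorylation, heat shock, immune effectors, apoptosis, glutathione S-transferases, cytochrome P450 enzymes, fat body, gut, muscle, neurons, hemocytes, testis, and spermatheca and oviduct. Of the 33, the 31 with at least 3 tested members were tested with limma 3.58.1's camera, two-sided, at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and adjusted over the lists. Called members are given over all genes and adjusted over the list alone. A further 7 lists were written after the values had been seen and are adjusted over those 7.

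Fisher's exact test, two-sided, compared called with tested genes within 2 Mb of Ipo9. The alternatives were relative log expression factors, no composition factor, DESeq2 1.42.0, limma-voom, no filter beyond 1 count, a filter of at least 1 CPM in 3 libraries, a fold of at least 2, a replicate block, each library left out, windows of 1 and 5 Mb and the whole arm 3R, camera with an estimated correlation, and the rotation test fry. Leaving out both replicates numbered 2 was added after the data were seen. The scripts were tested on simulated counts with the means, dispersions and library sizes of these 6 libraries and 200 changed genes among 8110 in each of 5 runs. At a fold of 1.2, 40.8% of the changed genes were recovered, 76.4% at 1.5, 84.8% at 2 and 91.6% at 3, and 61 of 795 calls were false (7.67%). Tests for the closing section used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. No library was left out of the main comparison.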

Results

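Poly(A) RNA from dissected fly ovaries was sequenced in 6 directional libraries, 3 from mutant and 3 from control females kept at 25 °C. The mutant females carried the RanBP9 allele D1 over the chromosomal deficiency BSC469, and the control females carried the chromosome of the standard laboratory strain w1118 over the same deficiency. RanBP9 is the older name of Ipo9, which encodes Importin-9, a transport receptor known to carry actin into the nucleus. The series asks how a lower level of nuclear actin affects transcription. Mutant replicates 1, 2 and 3 held 25700339, 21899204 and 22126162 counted reads, and control replicates 1, 2 and 3 held 26483578, 21583524 and 23815658, over 17559 genes in each library. The labels do not say whether replicates came from separate crosses or dissections. The p-values of single genes from the fits therefore measure the spread between libraries and nothing wider. Fisher's exact and permutation p-values take genes as the units, and camera compares genes of a list with the other genes of these same libraries. Exact counting p-values, and intervals and floors on counts, cover counting error only.

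Ipo9 (FBgn0037894), a protein-coding gene at 11412522 to 11416142 on the plus strand of chromosome arm 3R in the BDGP6 (dm6) build, was expressed in every library. Its counts were 2513, 1980 and 2062 in mutant replicates 1 to 3 and 3128, 3375 and 2733 in control replicates 1 to 3. The scaled level, in CPM (counts scaled to a common library total), was 93.8 ± 3.91 in mutant and 130 ± 22.1 in control ovaries (mean ± SD, n = 3 each), and every mutant library lay below every control library. The log2 fold change of Ipo9 was −0.47 (SE 0.12), with an adjusted p of 0.0544 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, just short of the threshold of 0.05. Control replicate 2 stood apart at 155 CPM, against 118 and 116 in control replicates 1 and 3. Without that library, Ipo9's log2 fold change was −0.32 and its adjusted p 0.00551, past the threshold. DESeq2's Wald test on all 6 libraries also placed Ipo9 past it, at −0.47 with an adjusted p of 1.2e-04, and so did limma-voom, at −0.45 with an adjusted p of 0.0235.

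None of the 4 actin genes with enough counts to test passed the threshold, nor did any when adjusted over the list alone. Act5C (FBgn0000042), the main cytoplasmic actin, was at 2763 ± 18.3 CPM in mutant and 2934 ± 178 in control ovaries (SD, n = 3), a log2 fold change of −0.09 (SE 0.05, adjusted p = 0.282, edgeR). It lies at 5900861 to 5905399 on chromosome X. Act42A (FBgn0000043), the other cytoplasmic actin, at 6013910 to 6015689 on 2R, had a log2 fold change of 0.06 (SE 0.06, adjusted p = 0.550). The muscle actins Act57B and Act87E had log2 fold changes of 0.21 (SE 0.33) and 0.36 (SE 0.30), and Act79B and Act88F had too few counts to test. Act57B overlaps a snoRNA gene on the same strand, so its value is uncertain. The median over the 4 was 0.14, with a camera adjusted p of 0.867. The same side of the threshold held for these actins in every alternative run.

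**Figure D1:**
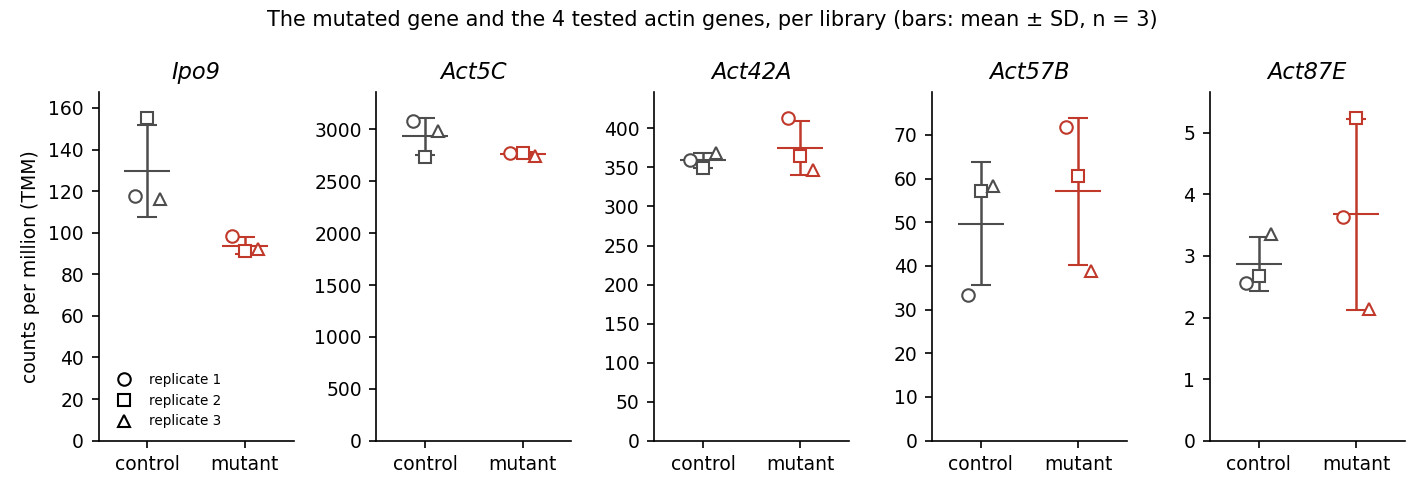
Scaled counts (CPM, vertical axes, linear, from 0) of Ipo9 and the 4 tested actin genes in each control and mutant library, with the mean and SD of 3 libraries as bars. Ipo9 was at 98.3, 91.1 and 92.0 in the mutant libraries and at 118, 155 and 116 in the control libraries, while the groups overlapped for the actins.

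Mutant ovaries had higher mRNA levels of 674 genes and lower levels of 503, together 1177 or 14.5% of the 8110 genes tested. Among the best-supported rises were Dad (FBgn0020493), an inhibitor of the Dpp signal, with a log2 fold change of 1.21 (SE 0.06), the amino acid transporter gene slif (FBgn0037203) at 0.81 (SE 0.04), and Naglu (FBgn0014417), a lysosomal glucosaminidase gene, at 0.71 (SE 0.04). Dad rose from 18.8 ± 0.659 to 43.5 ± 1.64 CPM and Naglu from 166 ± 6.10 to 273 ± 1.79 (SD, n = 3). Among the best-supported falls were CG12099 at −1.36 (SE 0.07), the exchanger gene zyd (FBgn0265767) at −1.54 (SE 0.08) and Idgf2 (FBgn0020415), which encodes a chitinase-like growth factor, at −1.48 (SE 0.09). zyd fell from 99.8 ± 7.38 to 34.3 ± 3.14 CPM, and Idgf2 from 67.0 ± 4.04 to 24.0 ± 2.96. The edgeR adjusted p was 7.4e-06 for each of Dad, slif, Naglu, CG12099 and zyd, and 2.1e-05 for Idgf2. Dad lies at 17054007 to 17070408 on 3R, slif at 22881045 to 22893821 on 3L, Naglu at 8408888 to 8411868 on 2L, CG12099 at 1555363 to 1558484 on 3L, zyd at 23023317 to 23035550 on X and Idgf2 at 16447330 to 16450508 on 2L, each annotated as a protein-coding gene.

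Among called genes with a mean of at least 5 CPM, the largest rises were those of CG13321 (3.20, SE 0.69), the ribosomal RNA precursor gene pre-rRNA:CR45856 (2.43, SE 0.49), the snoRNA host gene Uhg5 (2.31, SE 0.19) and the small heat shock protein gene Hsp23 (1.85, SE 0.15), all as log2 fold changes with adjusted p between 9.3e-05 and 0.0424. CG10654 (1.65) and Rpt3R (from 3.19 ± 1.21 to 9.14 ± 1.58 CPM), a paralog of a proteasome ATPase gene, followed. Among genes with a proper symbol, the next were pon (1.44), which encodes a partner of the cell fate determinant Numb, and Oseg4 (1.38), a gene of intraflagellar transport. The largest fall among these genes was that of CG13032, with 338, 301 and 333 counts in the control libraries and 0, 2 and 1 in the mutant libraries, a ratio of 315 (exact 95% counting interval 107 to 1528). CG42857 (−4.69), the adhesion molecule gene Dscam4 (−4.05), CG6908 (−3.56), the anion exchanger gene Ndae1 (−2.67), the germline differentiation gene tut (−1.92) and the cytochrome P450 gene Cyp4g1 (−1.58) fell as well. CG6908 lies inside the stretch of 3R where control replicate 2 was high. Uhg5, pre-rRNA:CR45856, Oseg4, Ndae1 and Cyp4g1 overlap other genes on the same strand, so their values are uncertain. The calls of CG13321 and pre-rRNA:CR45856 ended without some of the libraries, at adjusted p of up to 0.132 for CG13321 without control replicate 2 and 0.181 for pre-rRNA:CR45856 without control replicate 1, and that of Cyp4g1 ended at 0.0557 without mutant replicate 3.

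Most called changes were small. The median fold was 1.22 among the rises and 1.23, as control over mutant, among the falls, and 100 rises and 85 falls reached a fold of at least 2. The groups did not overlap in any of the 1177 genes, nor in 2830 of all genes tested (34.9%), where chance gives 10%. The median log2 fold change over all genes tested stayed within 0.01 of 0 under each scaling. Each scaling sets a gene against the other counts of its own library, so a change in total mRNA could not be seen. Of the 3 most abundant tested genes, the mitochondrial rRNA gene mt:lrRNA (−0.09) and the elongation factor gene eEF1alpha1 (0.13) did not pass the threshold, and the chorion gene Cp38 did. mt:lrRNA and eEF1alpha1 overlap genes of small RNAs on the same strand. The mutant libraries lay at −25.0, −7.92 and −27.3 on the first principal component, which held 58.1% of the variance, and the control libraries at 22.2, 16.7 and 21.3. On the second, which held 19.3%, mutant replicate 2 lay at −26.1 and the other 5 libraries at 0.690 to 10.8. The count of calls fell to 566 without control replicate 1, 739 without mutant replicate 2, 775 without control replicate 3 and 778 without mutant replicate 1, each more than 1.5 times below 1177. Without both replicates numbered 2, a choice made after the data were seen, 516 genes passed, 243 higher and 273 lower, so that 47.1% of the calls were rises instead of 57.3%.

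**Figure D2:**
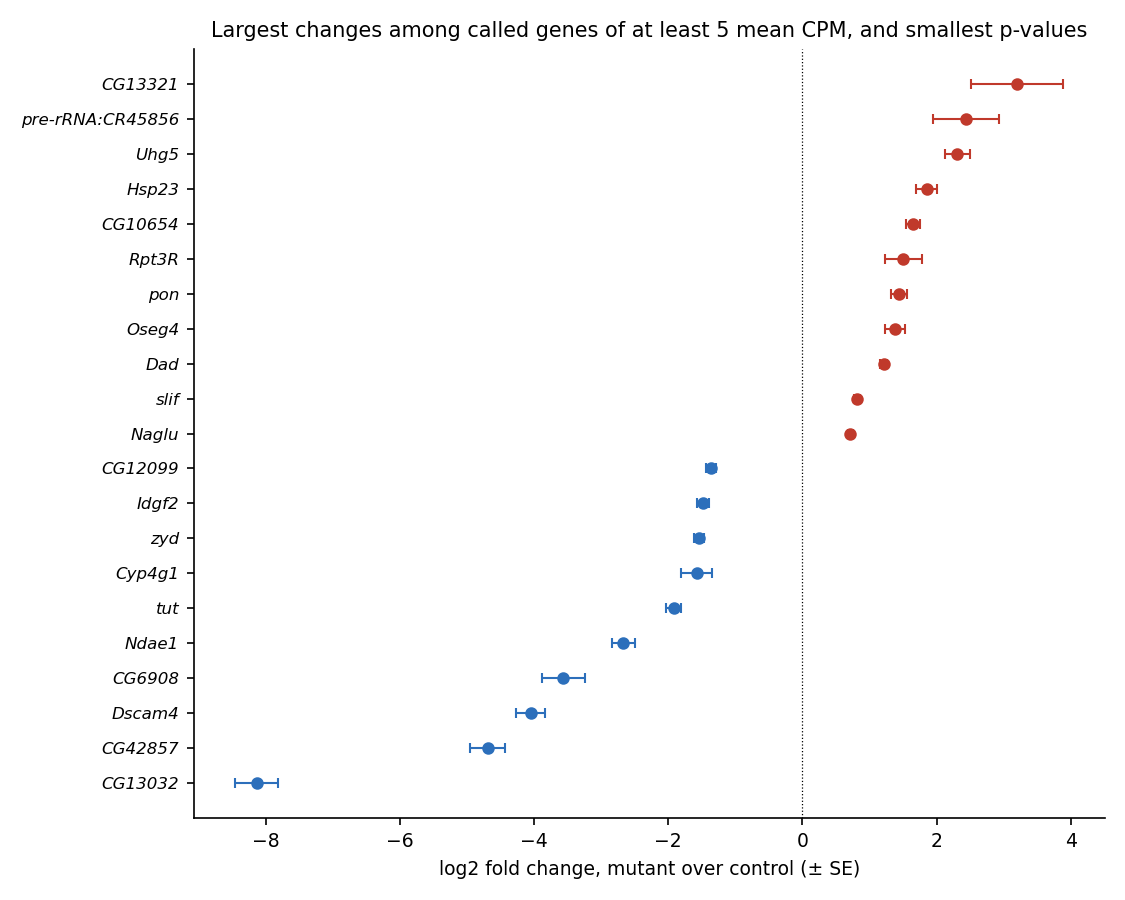
Log2 fold change of mutant over control (horizontal axis, with the standard error as bars) for the genes with the largest changes among called genes with a mean of at least 5 CPM and the called genes with the smallest p-values, from 3 libraries per group. Rises run from Naglu at 0.71 to CG13321 at 3.20, and falls from CG12099 at −1.36 to CG42857 at −4.69 and to CG13032, whose −8.13 rests on 3 counts in the mutant libraries.

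Among genes for ribosomal proteins, initiation factors and the chaperonin, every called gene was higher, by small amounts. Of 86 tested genes for cytosolic ribosomal proteins, 50 were higher, 0 lower and 36 not past the threshold (72 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.19. RpL7A, a protein of the large subunit, rose by 0.27 (SE 0.04), from 2326 ± 58.6 to 2796 ± 35.0 CPM, RpS26 by 0.27 (SE 0.05) and RpS14b by 0.25 (SE 0.04), with edgeR adjusted p of 0.00234, 0.0046 and 0.0036. RpL7A overlaps a snoRNA gene on the same strand. The list's median lay at 0.19, 0.24 and 0.13 in mutant replicates 1, 2 and 3, relative to the control mean, and at −0.05 to 0.05 in the control libraries. Of 35 translation initiation factor genes, 5 were higher and 0 lower (7 and 0 adjusted over the list alone), among them eIF2A at 0.33 (SE 0.04, adjusted p = 6.0e-04), with a list median of 0.07. Of the 8 genes for the chaperonin that folds actin and tubulin, 3 were higher and 0 lower (5 and 0 adjusted over the list alone), CCT4 by 0.29 (SE 0.04), CCT3 by 0.19 (SE 0.04) and CCT7 by 0.18 (SE 0.04). The calls of CCT3 and CCT7 ended without control replicate 1, at adjusted p of 0.0788 and 0.0802.

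Camera with its preset correlation placed the cytosolic ribosomal protein list (adjusted p = 5.8e-17), the initiation factors (0.00653) and the chaperonin (0.0163) past the threshold, and none of these calls held with an estimated correlation (adjusted p = 0.904 with an estimated correlation for each). The chaperonin call ended without mutant replicate 3 (0.0540), without control replicate 2 (0.0622) and without both replicates numbered 2 (0.0532), and the initiation factor call ended without both replicates numbered 2 (0.0955). Mitochondrial ribosomal protein genes had 6 of 74 higher and 0 lower (2 and 0 adjusted over the list alone), with a median of 0.06 and a camera adjusted p of 0.0197, again 0.904 with an estimated correlation. That call ended without mutant replicate 2 (0.0583), mutant replicate 3 (0.115), control replicate 1 (0.0791) or control replicate 2 (0.263), and without both replicates numbered 2 (0.386). Oxidative phosphorylation genes had 2 of 67 higher and 0 lower, ND-B14 by 0.43 (SE 0.06) and SdhA by 0.14 (SE 0.03), a complex I and a complex II subunit, with 1 and 0 adjusted over the list alone, a median of 0.03 and a camera adjusted p of 0.0861, which was 0.00675 without mutant replicate 1 and 4.0e-04 without control replicate 3. SdhA's call ended without each library but mutant replicate 3, at adjusted p of up to 0.0940. None of the 32 proteasome subunit genes passed the threshold, with a median of 0.05 and a camera adjusted p of 0.206, which was 0.00576 without control replicate 3.

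**Figure D3:**
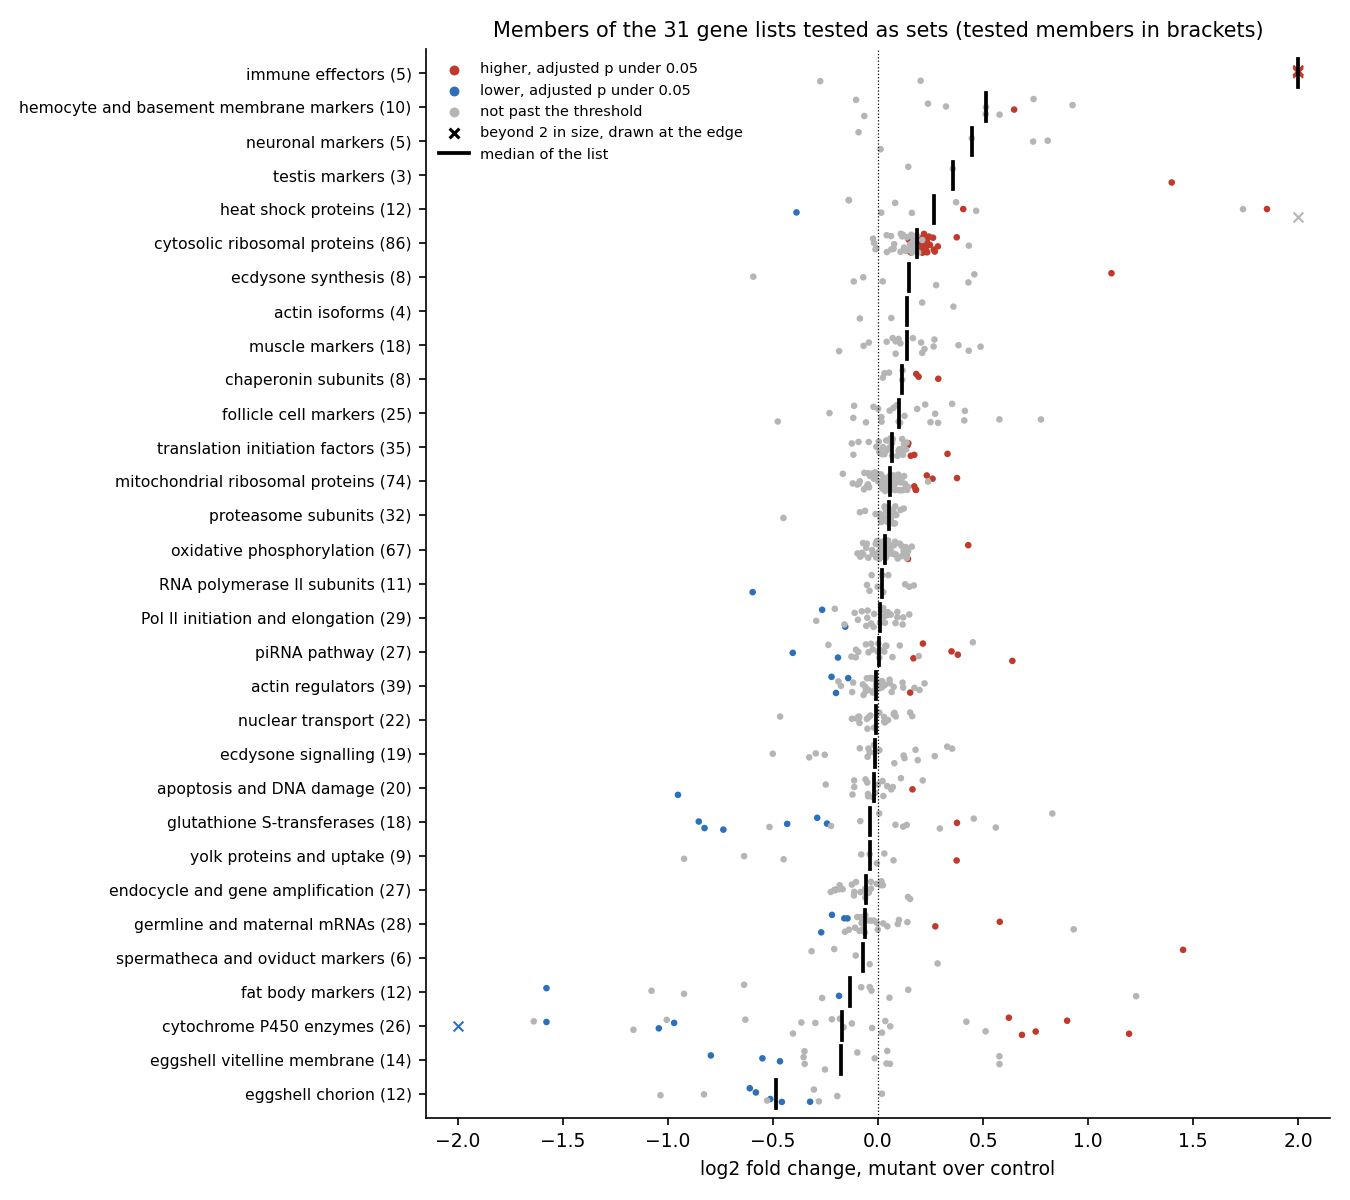
Log2 fold change of mutant over control (horizontal axis) for each tested member of the 31 gene lists tested as sets, with the list median as a black bar, rises in red, falls in blue and genes not past the threshold in grey, from 3 libraries per group. The cytosolic ribosomal proteins have 50 of 86 members called higher around a median of 0.19, and the chorion genes 5 of 12 called lower around −0.49.

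Follicle cells make eggshell mRNAs late in oogenesis. Of 12 chorion genes tested, 0 were higher, 5 lower and 7 not past the threshold (0 and 6 adjusted over the list alone), with a median log2 fold change of −0.49. Cp38 fell from 8554 ± 1199 to 5603 ± 458 CPM (−0.61, SE 0.11), Cp19 from 2446 ± 121 to 1781 ± 189 (−0.46, SE 0.07) and Cp16 from 1006 ± 79.4 to 705 ± 76.2 (−0.51, SE 0.09), with edgeR adjusted p of 0.0154, 0.00536 and 0.00946. Camera gave the chorion list an adjusted p of 0.00153, and 0.904 with an estimated correlation. The list median was −0.38, −0.49 and −0.63 in mutant replicates 1 to 3 relative to the control mean, and 0.10, −0.24 and 0.14 in control replicates 1 to 3, so control replicate 2 lay nearest to the mutants. Cp38's call ended at an adjusted p of 0.0523 without mutant replicate 2 and 0.0508 without control replicate 1. Of 14 vitelline membrane genes, which code for the inner eggshell layer, 3 were lower and 0 higher (4 and 0 adjusted over the list alone), with a median of −0.18 and a camera adjusted p of 0.252. These were Vm26Ab (−0.47, SE 0.11), Vm34Ca (−0.55, SE 0.12) and Vm32E (−0.80, SE 0.18), and each call ended without control replicate 1, at adjusted p of 0.0984, 0.0963 and 0.151, among other libraries. Vm32E overlaps another gene on the same strand.

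Follicle cell and endocycle genes did not pass as groups. None of the 25 follicle cell markers passed (median 0.10, camera adjusted p = 0.255), but their median lay at 0.30 and 0.13 in mutant replicates 1 and 2 and at −0.14 in mutant replicate 3, and camera gave 4.4e-04 without mutant replicate 3. Muscle markers ran the same way over these libraries, at medians of 0.49, 0.29 and −0.31, and so did hemocyte markers, at 0.85, 0.60 and −0.12. Of 27 endocycle and gene amplification genes, the replication helicase gene Mcm7 was lower (−0.20, SE 0.06) and 0 were higher (0 and 0 adjusted over the list alone), with a median of −0.06 and a camera adjusted p of 0.0842, which was 0.00141 without mutant replicate 3 and 0.0464 with DESeq2. Mcm7's call ended without each library but mutant replicate 3, at adjusted p of up to 0.136. Of 9 yolk protein and uptake genes, the lipophorin receptor gene LpR1 was higher (0.37, SE 0.06, adjusted p = 0.00257) and 0 were lower (1 and 1 adjusted over the list alone), with a median of −0.04 and a camera adjusted p of 0.794. The yolk protein genes Yp1, Yp2 and Yp3 were at −0.08, −0.04 and −0.64 (SE 0.15 for Yp3, adjusted p = 0.0539), none past the threshold, and the groups did not overlap for Yp3.

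Germline mRNAs moved both ways. Of 28 germline and maternal mRNAs, 2 were higher and 4 lower (3 and 6 adjusted over the list alone), with a median of −0.06, a mean of 0.01 and a camera adjusted p of 0.206. The exon junction gene mago rose by 0.58 (SE 0.05, adjusted p = 1.0e-04), and egl, an adaptor gene for mRNA transport by dynein, fell by 0.22 (SE 0.04, adjusted p = 0.0111). Of 27 piRNA pathway genes, 5 were higher and 2 lower (6 and 4 adjusted over the list alone), with a median of 0.01 and a camera adjusted p of 0.704. The Tudor domain gene BoYb rose by 0.35 (SE 0.05, adjusted p = 0.0026), and squ, which overlaps another gene on the same strand, rose by 0.38 (SE 0.08). The call of squ ended at adjusted p of 0.0567 without control replicate 2 and 0.0684 without control replicate 3. Of 8 ecdysone synthesis genes, nvd, which encodes the oxygenase that starts the pathway, rose by 1.11 (SE 0.15, adjusted p = 0.00126) and 0 were lower (1 and 1 adjusted over the list alone), with a median of 0.15 and a camera adjusted p of 0.616. None of the 19 ecdysone signalling genes passed (median −0.02, mean 7.8e-04, camera adjusted p = 0.851).

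Genes of actin regulation, nuclear transport and transcription showed few changes. Of 39 actin regulators, 1 was higher and 3 lower (0 and 1 adjusted over the list alone), with a median of −0.01 and a camera adjusted p of 0.742. The formin gene dia fell by 0.22 (SE 0.05), the myosin light chain gene sqh by 0.20 (SE 0.06) and the ring canal gene kel by 0.14 (SE 0.04), and the capping protein gene cpa rose by 0.15 (SE 0.04). Each of these 4 calls ended without control replicate 1, among other libraries, at adjusted p of 0.0732 for dia, 0.132 for sqh, 0.146 for kel and 0.146 for cpa. Mrtf and bs, the genes of the actin-sensing coactivator and its partner serum response factor, had log2 fold changes of 0.02 (SE 0.05) and −0.01 (SE 0.06), both short of the threshold and too few for a set test, and bs overlaps a tRNA gene on the same strand. None of the 22 nuclear transport genes passed, Ipo9 included (median −0.01, camera adjusted p = 0.775). Of 11 RNA polymerase II subunit genes, Polr2B (FBgn0262955), a subunit of the catalytic core at 14125791 to 14130111 on 3R, fell from 202 ± 11.0 to 134 ± 5.84 CPM (−0.60, SE 0.05, adjusted p = 9.3e-05), and the other 10 did not pass. The list had 0 higher and 1 lower adjusted over the list alone, a median of 0.02, a mean of −0.02 and a camera adjusted p of 0.867. Of 29 initiation and elongation genes, Tbp, the TATA-binding protein gene, fell by 0.27 (SE 0.05, adjusted p = 0.00874) and MED1, a Mediator subunit gene, by 0.16 (SE 0.05), and 0 were higher. That list had 0 higher and 1 lower adjusted over the list alone, a median of 0.01, a mean of −0.02 and a camera adjusted p of 0.794. MED1's call ended without control replicate 1 (0.185) and 3 other libraries.

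Stress, immune and detoxification genes differed gene by gene. Of 12 heat shock genes, 2 were higher and 1 lower (4 and 1 adjusted over the list alone), with a median of 0.27 and a camera adjusted p of 0.199. Hsp23 rose from 4.90 ± 1.09 to 17.6 ± 2.01 CPM and Hsp83, which encodes the fly Hsp90 chaperone, from 4013 ± 103 to 5316 ± 107 (0.41, SE 0.04, adjusted p = 2.7e-04), whereas Hsp26 fell by 0.39 (SE 0.05, adjusted p = 0.00149). The heat shock genes that did not pass the filter on low counts were chiefly Hsp70Bb. They summed to 96, 45 and 5 counts in mutant replicates 1 to 3 and to 5, 9 and 4 in control replicates 1 to 3. Without mutant replicate 3 the heat shock list had a camera adjusted p of 0.0111, with DESeq2 0.0219 and with no filter beyond 1 count 0.0211. Of 5 immune effector genes tested, the antimicrobial peptide genes Dro, AttA and Def were higher and 0 lower (3 and 0 adjusted over the list alone), with a median of 2.73 and a camera adjusted p of 0.0670, which was 6.9e-04 without mutant replicate 1 and 0.0245 without control replicate 1. Dro rose from 0.276 ± 0.174 to 1.81 ± 0.490 CPM (adjusted p = 0.00356), and AttA had 15, 30 and 11 counts in the mutant and 1, 1 and 0 in the control libraries, a ratio of 28.8 (exact 95% counting interval 7.62 to 244). Def's call ended without control replicate 1, at an adjusted p of 0.105, and without 3 other libraries. Untested immune effectors summed to 34, 1285 and 644 counts in mutant replicates 1 to 3 and to 67, 37 and 35 in control replicates 1 to 3. Drs held 1155 and 596 of these counts in mutant replicates 2 and 3, and other genes led in the other libraries. Gut markers were also highest in mutant replicates 2 and 3, at 5206 and 673 counts.

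Of 20 apoptosis and DNA damage genes, the cell death gene hid was lower, from 25.9 ± 1.25 to 13.4 ± 1.42 CPM (−0.95, SE 0.09, adjusted p = 1.4e-04), and the caspase inhibitor gene Diap1, whose product Hid antagonises, higher (0.16, SE 0.04), with 1 and 1 adjusted over the list alone, a median of −0.02 and a camera adjusted p of 0.693. Diap1's call ended without control replicate 1 (0.125) and 3 other libraries. Of 18 glutathione S-transferase genes, 1 was higher and 6 lower (4 and 6 adjusted over the list alone), with a median of −0.04 and a camera adjusted p of 0.693. GstE1 rose by 0.38 (SE 0.05), and GstD1 fell by 0.29 (SE 0.04), GstD3 by 0.43 (SE 0.06) and GstE8 by 0.74 (SE 0.11). Of 26 cytochrome P450 genes, 5 were higher and 4 lower (5 and 5 adjusted over the list alone), with a median of −0.17 and a camera adjusted p of 0.353. Cyp6a17 had 2, 0 and 0 counts in the mutant and 134, 165 and 141 in the control libraries, a ratio of 214 (exact 95% counting interval 58.8 to 1769), while Cyp6d4 rose by 0.90 (SE 0.13) and Cyp6a9, a neighbour of Cyp6a17, by 0.69 (SE 0.13). Reads of these recently duplicated gene families can be shared between copies, which leaves their values uncertain.

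mRNAs of other tissues that a dissected ovary sample can hold differed between single libraries. None of the 33 gut markers passed the filter on low counts, so none was tested. Yet they summed to 6, 5206 and 673 counts in mutant replicates 1 to 3 and to 13, 7 and 5 in control replicates 1 to 3. The protease gene Jon65Aiv was at 1379 counts in mutant replicate 2 and the mannosidase gene LManVI at 310 in mutant replicate 3. Counts of the Malpighian tubule mRNA Uro were 0, 248 and 0 in mutant replicates 1 to 3 and 142, 45 and 78 in control replicates 1 to 3. Of 12 fat body markers, Cyp4g1 and the fatty acid ligase gene bgm were lower and 0 higher (4 and 1 adjusted over the list alone), with a median of −0.13 and a camera adjusted p of 0.252. The call of bgm ended without control replicate 2 (0.140) and 4 other libraries. Of 10 hemocyte and basement membrane markers, SPARC, which encodes a collagen-binding matrix protein, rose by 0.65 (SE 0.10, adjusted p = 0.00264) and 0 were lower (1 and 0 adjusted over the list alone), with a median of 0.51 and a camera adjusted p of 0.200. The median of that list was 0.85 and 0.60 in mutant replicates 1 and 2 and −0.12 in mutant replicate 3, and camera gave 0.00141 without mutant replicate 3.

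None of the 18 muscle markers (median 0.14, camera adjusted p = 0.693, with −0.51, 0.23 and 0.27 in control replicates 1 to 3) and none of the 5 neuronal markers (median 0.45, camera adjusted p = 0.693) passed. Of 3 testis markers, betaTub85D was higher (1.40, SE 0.36) and 0 lower (1 and 0 adjusted over the list alone), with a median of 0.36 and a camera adjusted p of 0.200. Of 6 spermatheca and oviduct markers, Est-6 was higher (1.45, SE 0.37) and 0 lower (1 and 0 adjusted over the list alone), with a median of −0.07, a mean of 0.18 and a camera adjusted p of 0.867. The betaTub85D call ended without control replicate 1 (0.107) and 4 other libraries, and the Est-6 call without control replicate 1 (0.106) and 3 other libraries, at levels under 1 CPM in both groups.

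**Figure D4:**
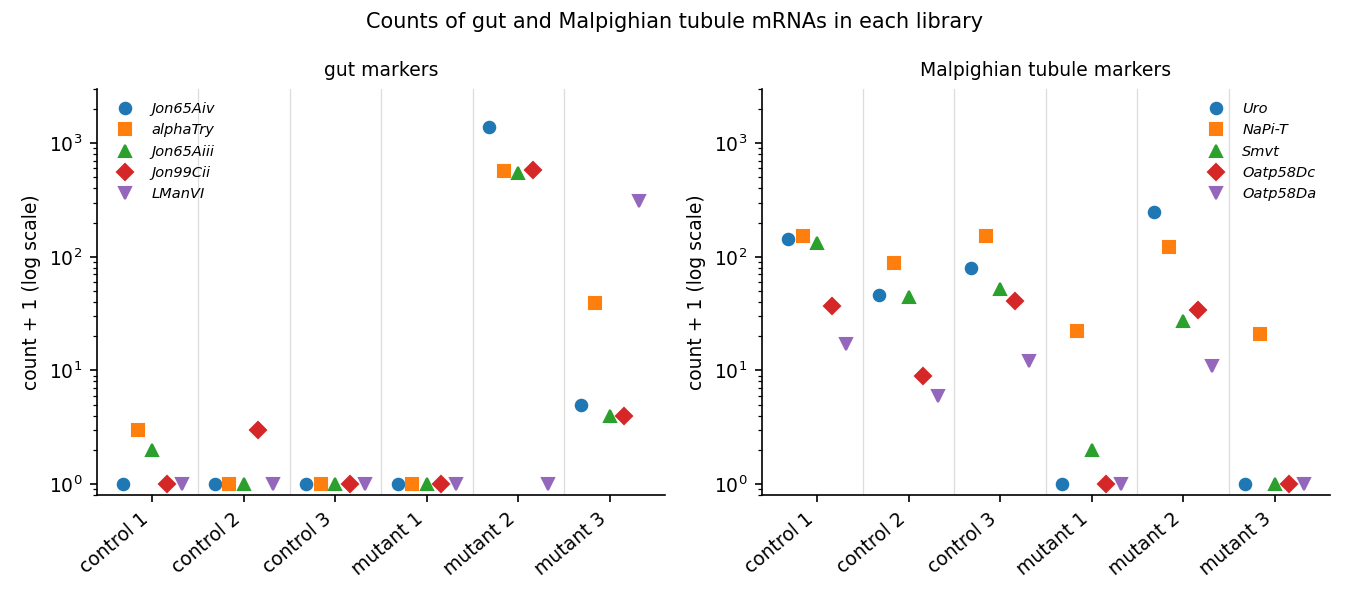
Raw counts plus 1 (vertical axes, log scale) of 5 gut mRNAs and 5 Malpighian tubule mRNAs in each of the 6 libraries. Jon65Aiv reaches 1379 counts in mutant replicate 2 and 4 in mutant replicate 3, and Uro lies at 0 in mutant replicates 1 and 3.

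Counting calls of any size, the share of called genes around the mutated gene was close to the share of tested genes there. Within 2 Mb of Ipo9, 51 of 328 tested genes were called, which is 4.33% of all calls against 4.04% of the genes tested (Fisher's exact test, two-sided, p = 0.576). Of the largest changes named above, Rpt3R, CG42857 and CG6908 lie in this window and the others outside it. Whether large changes gather there was not tested. The shares called were 12.2% on chromosome X, 14.8% on 2L, 14.9% on 2R, 15.9% on 3L, 14.5% on 3R and 17.1% on 4. The share within 2 Mb was 6.01% without control replicate 1 (Fisher's exact p = 0.0202) and 6.4% without both replicates numbered 2 (Fisher's exact p = 0.00784). With a replicate block it was 5.77% (Fisher's exact p = 0.0175), and each of these was past the threshold. Around Ipo9 the control libraries themselves differed. Over the 41 tested genes centred on Ipo9, control replicate 2 lay at a median of 0.24 on the log2 scale above the mean of the other control libraries, and Ipo9 itself lay 0.41 higher.

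**Figure D5:**
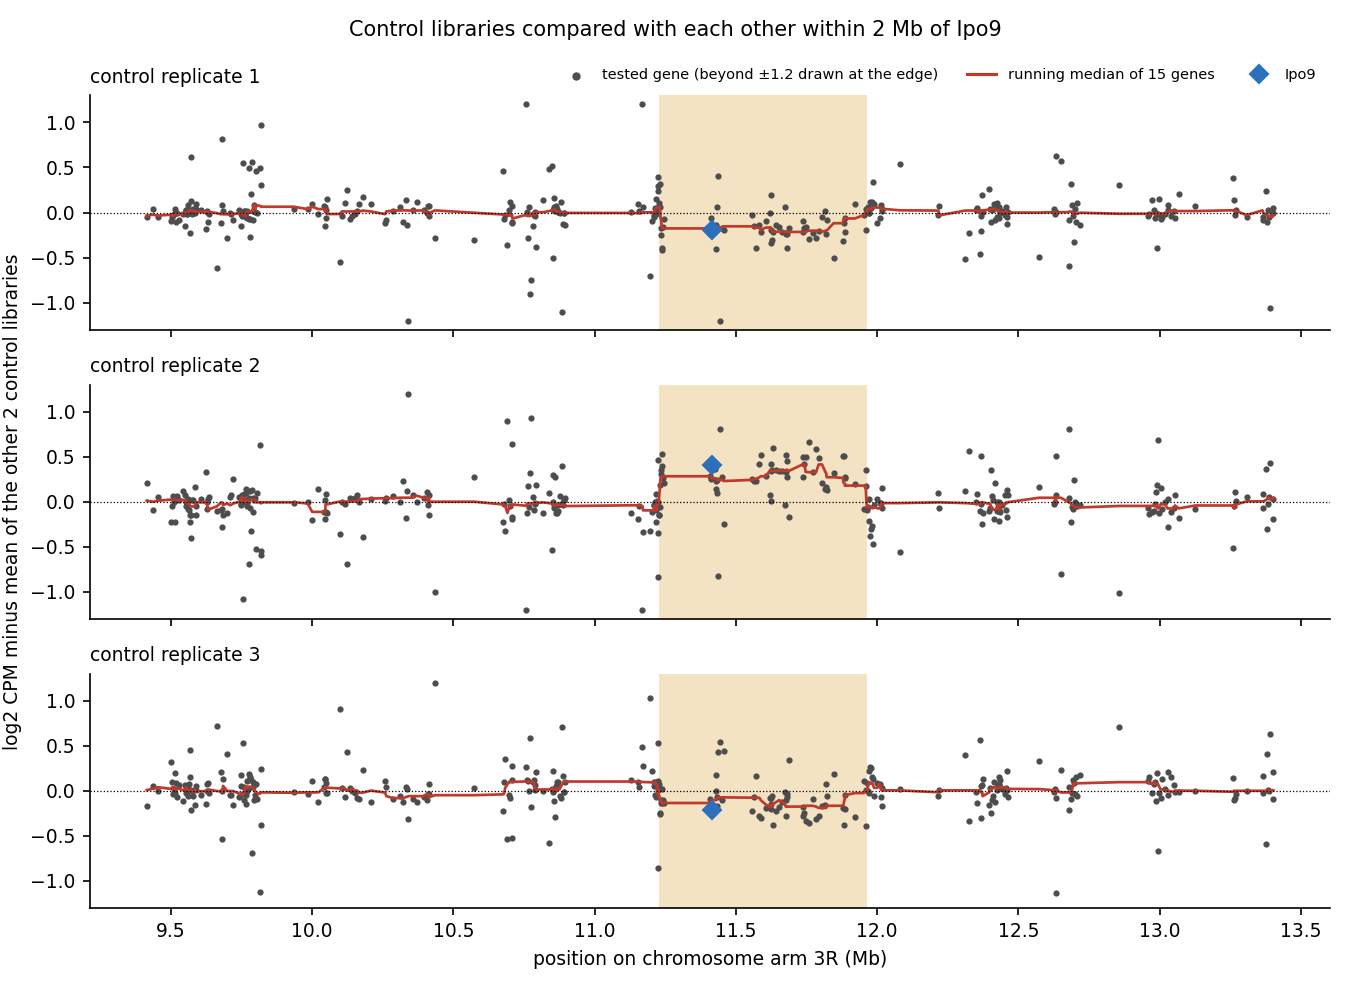
Log2 CPM in each control library minus the mean of the other control libraries (vertical axis) for tested genes within 2 Mb of Ipo9, by position on chromosome arm 3R in Mb, with a running median of 15 genes in red and Ipo9 as a blue diamond. The shaded stretch from 11230617 to 11960909 was bounded by a running median of at least 0.15 in control replicate 2, and since each library is set against the others, the values of the 3 libraries sum to 0 for each gene.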

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

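The tests of the region around Ipo9, of sampling noise in the nearly absent genes, of composition scaling and of other splits of the libraries were chosen only after the results were seen, and the other tests of the nearly absent genes and those of length and expression and of egg chamber stage were written before their results. The germarium list that the egg chamber test uses was itself written after values had been seen.

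List members set aside by the filter on low counts held counts above every control library in single mutant libraries. Genes with high counts in 1 library alone did not pass that filter, such as Jon65Aiv with 1379 counts in mutant replicate 2. Gut markers summed to 5206 counts in mutant replicate 2 and 673 in mutant replicate 3. Untested heat shock genes summed to 96 in mutant replicate 1 and 45 in mutant replicate 2. Untested immune effectors summed to 1285 in mutant replicate 2 and 644 in mutant replicate 3, and untested spermatheca and oviduct markers to 80 in mutant replicate 3. The control libraries held at most 13, 9, 67 and 8 counts of these 4 groups. Only mutant libraries above the controls were flagged, and the reverse also occurred. Untested fat body markers summed to 32 counts in control replicate 2, against 7, 7 and 1 in mutant replicates 1 to 3. Pxd, untested in the chorion list, had 6, 10 and 4 counts in control replicates 1 to 3 and 2, 0 and 0 in mutant replicates 1 to 3.

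Genes around Ipo9 were higher in control replicate 2 than in control replicates 1 and 3. Over the 41 tested genes centred on Ipo9, at 11216535 to 11628452 on 3R, the median was 0.24 higher on the log2 scale (bootstrap 95% interval 0.135 to 0.282), and 0 of 10000 expression-matched gene sets, or 0%, came as high (highest 0.10), which argues against spread that follows expression level. No biological explanation was tested, since the pattern lies within the control group. A candidate explanation is that some of the control replicate 2 flies carried 2 copies of the region, as flies without the deficiency would. Of 191 other windows of 41 genes, 0.524% had a median as high, the adjacent window at 11628759 to 12003516 alone, and the limits of the deficiency are not in the labels, so this stays a hypothesis.

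Some called genes were nearly absent from all 3 libraries of a group, each at under 5% of the lowest library of the other group in CPM, 6 from control (CG42329, CG18853, SerT, CG6912, asRNA:CR45600 and Ssl2) and 3 from mutant ovaries (Cyp6a17, CG13032 and CR41509), chosen after their values were seen. SerT was at least 30.2-fold and CG42329 at least 23.3-fold higher in mutant ovaries, and CR41509 at least 35.0-fold lower, while CG6912 and asRNA:CR45600 overlap each other on the same strand, so their values are uncertain and may be 1 signal. The exact counting p of these genes, Bonferroni adjusted over all genes tested, was at most 1.0e-17. The cut that picked them already asks for counts far apart, so this p could not come out high. It is therefore no separate test of sampling noise. Their median count in the group with expression, 54, was the value first meant for this, but the filter on low counts holds it up. Of these genes, 55.6% lay on chromosomes other than 3 (exact 95% interval 21.2% to 86.3%). With CG6912 and asRNA:CR45600 counted once and without CR41509, annotated on the Y, which females lack, it was 4 of 7 (18.4% to 90.1%). With the cut on group means it was 7 of 15 (21.3% to 73.4%). These shares argue against sequence on chromosome 3 that acts only on genes of that chromosome as the whole cause. They do not bear on linked sequence that acts on genes of other chromosomes. Sequence differences between the fly stocks over the whole genome cannot be told apart from the allele, since each group holds 1 genotype. Adjacent tested genes were called in the same direction in 105 pairs, against a mean of 86.4 in 10000 permutations within chromosome arms (permutation p = 0.0191). The permutations take neighbouring genes as independent, and neighbours that overlap or change together would also give such pairs. The cause of that clustering was not tested.

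Cytosolic ribosomal protein mRNAs were higher in mutant ovaries, with a median of 0.19. Their exons span a median of 922 bp against 2150 bp over all genes tested, but 0 of 10000 lists matched on exon length and expression, or 0%, had a median as high (highest 0.07). This argues against length or expression bias as far as the drawn genes match, and how closely they do is not given. The draws take genes as independent, while the list's estimated correlation was 0.727, so their range is likely too narrow. The list's median lay 0.19 above that of the other 8024 genes tested (bootstrap 95% interval 0.173 to 0.203). A scaling factor moves all genes of a library alike, so it cannot make or remove this difference. The scaling also holds the other genes near 0 (median −0.00497). The counts therefore show a rise relative to the other genes. They cannot tell it from a fall of the other mRNAs, so composition is not decided. A lower share of late egg chambers may contribute, as chorion mRNAs were lower, but the germarium mRNAs that would then be higher had a median of −0.00929 (bootstrap 95% interval −0.26 to 0.93), too wide to decide. The mutant allele stays open as an untested biological explanation.

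The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1177 genes and the highest of the others 0, and the real split was the only 1 of the 10 with as many.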

How the results depend on the processing

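Leaving out both replicates numbered 2 was chosen after the data were seen, and all other alternatives were planned. The 1177 calls (674 higher, 503 lower) stayed within 1.5 times under other scalings, DESeq2, limma-voom and other filters, at 1121 to 1270, and 1026 to 1154 of the calls were shared. No list or named gene past the threshold changed direction in any alternative run, and of those short of it, 35 list values and 13 gene values changed sign, 0 of them under another scaling. A fold of at least 2 left 185 genes (100 higher, 85 lower), by construction. Leaving out 1 library gave 566 to 1475 genes, 319 to 861 higher and 247 to 614 lower, with fewer samples per fit. Without both replicates numbered 2 there were 516 genes, 243 higher and 273 lower, of which 427 were shared with the full set. Ipo9's log2 fold change stood at −0.54 to −0.32 with 1 library left out and passed the threshold without control replicate 2 (−0.32), without both replicates numbered 2 (−0.30), with DESeq2 (−0.47) and with limma-voom (−0.45), and the cause of the difference between tools was not tested. The count of gene lists past the threshold was 5, with 3 to 7 when 1 library was left out, 2 without both replicates numbered 2, 8 with DESeq2 (gut markers included, which were not tested in the full set), 2 with fry and 0 with an estimated correlation, where camera's smallest unadjusted p was 0.0669, and the cause was not tested. The share of calls within 2 Mb of Ipo9, 4.33%, ran from 4.07% to 6.01% with 1 library left out and reached 6.4% without both replicates numbered 2, and the cause was not tested. Over the 14 alternatives that refitted the counts, 410 list values stayed on their side of the threshold, 13 passed it newly and 9 lost it, and for named genes these counts were 1738, 52 and 204. Among set tests on the same fit, an estimated correlation ended all 5 list calls, and fry ended 4, kept that of the initiation factors and added immune effectors.

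Deviations of same-numbered libraries correlated at −0.23, −0.26 and −0.12, which gives no sign that replicate numbers pair the samples. These values cannot exclude a shared day or batch, which the labels do not give. With a replicate block 728 genes passed, 418 higher and 310 lower, and the share within 2 Mb of Ipo9 was 5.77% (Fisher's exact p = 0.0175), and the cause was not tested. Among the lists, only immune effectors changed their call with the replicate block (adjusted p = 0.0468).

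In simulated counts at these depths with 3 libraries per group and 200 changed genes among 8110, 40.8% of changes of 1.2-fold were recovered. The adjusted threshold depends on the share of changed genes, and the data gave 1177 calls, so recovery in the data may differ. Whether depth, the number of libraries or their spread limits this was not tested.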

Other observations

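The lists in this part were chosen after values had been seen, so their counts are not independent evidence, and their set tests were not planned.

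Of 42 ribosome biogenesis factor genes, 28 were higher and 0 lower, with a median log2 fold change of 0.21, among them Fib (0.27), the methyltransferase gene of the nucleolus, Nop56 (0.25) and Noc2 (0.25). Fib overlaps a snoRNA gene on the same strand. Camera gave an adjusted p of 5.7e-15, and the adjusted p = 0.193 with an estimated correlation. Of 18 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 10 were higher and 0 lower, with a median of 0.15, ValRS by 0.27 and AlaRS by 0.23 (camera adjusted p = 3.1e-06, and adjusted p = 0.275 with an estimated correlation). Of 13 glycolytic enzyme genes tested, 0 were higher and 6 lower, with a median of −0.21, including Pfk (−0.23), PyK (−0.22) and Gapdh1 (−0.21), the camera adjusted p being 9.1e-05, and the adjusted p = 0.275 with an estimated correlation.

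Of 17 condensin and replicative DNA polymerase genes, 0 were higher and 6 lower, with a median of −0.14, including Cap-D2 (−0.39), SMC2 (−0.27) and PolE2 (−0.27), with a camera adjusted p of 0.00605, and adjusted p = 0.454 with an estimated correlation. Of 19 autophagy genes, 0 were higher and 3 lower, Atg9 (−0.55), Atg18a (−0.36) and Atg8a (−0.34), with a median of −0.05, a camera adjusted p of 0.00667, and adjusted p = 0.275 with an estimated correlation. Of 13 germarium mRNAs, 4 were higher and 2 lower, with a median of −0.01 and a camera adjusted p of 0.434. The recombination genes vilya (1.09), mei-P22 (1.04) and narya (1.82), which overlaps another gene on the same strand, rose, as did c(2)M (0.20). Falls were those of c(3)G (−0.68), a gene of the synaptonemal complex, and bam (−0.27). Levels of vilya and narya were low, at 0.585 and 0.235 CPM in control and 1.26 and 0.849 in mutant ovaries. Members that did not pass went both ways, among them bgcn (0.93), mei-W68 (−0.78), rec (−0.17) and mei-218 (−0.01). Of 10 Malpighian tubule markers tested, 0 were higher and Dh44-R2 was lower (−0.48), with a median of −0.49, a camera adjusted p of 0.00196, and adjusted p = 0.291 with an estimated correlation. Counts of the tubule mRNA NaPi-T were 21, 121 and 20 in mutant replicates 1 to 3 and 151, 88 and 152 in control replicates 1 to 3. Log2 fold changes were negative for 9 of the 10 and positive for 1, Uro (0.06). They were small for ZnT35C (−0.06) and Prestin (−0.12). Dh44-R2 held 197, 200 and 169 counts in mutant replicates 1 to 3 and so did not follow NaPi-T over these libraries.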
